A study of Mus musculus with 21 samples.

How the data were processed

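RNA of mouse ES and TS cells was measured on 21 Affymetrix arrays, 3 in each of 7 groups, labelled with the WT Terminal Labeling Kit per the labels. The table holds 28946 probe sets of log2 values that the authors deposited, 1 column per array, and every column was used. Per the submitters' processing notes, the authors used Affymetrix Expression Console and the mouse build mm9; its version, the summarisation algorithm and the background correction are not given in the sources used here. The range of the values (array minimum 1.76 to 1.96, array maximum 14.27 to 14.48) is that of a log2 scale, and the array medians of 7.64 to 7.78 show values already brought to a like level. The deposited log2 values were therefore used without further normalization. Such arrays give no counts, so the precision is limited by the number of arrays, and dim probe sets understate changes because background adds to their signal.

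Samples were grouped by their titles. Probe sets were named from the annotation table of the array platform: 18286 had 1 gene, 1276 had several genes and 9384 were not listed. Symbols were updated through the gene ID for 18097 of the probe sets with 1 gene, and 189 kept the symbol of the platform table. The assembly GRCm38.p6 served only for symbols and chromosomes, and no coordinates are given because the authors' build is another. Of 17418 named genes, 489 had more than 1 probe set, and the one with the highest mean over all arrays was taken. Probe sets with several genes or none were not named. A probe set was kept if it lay above the 25th percentile of all values (6.29) on at least 3 arrays, which left 14660 genes. Of the fixed panel, Prl3d1, T, Krt8 and Xist had no probe set of a single gene above the filter and were not tested.

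The comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off), in 1 model of all 21 arrays with a mean per group. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the 14660 genes of a comparison, and a gene passed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The 11 comparisons were days 1 to 4 and each TS line against day 0, the ZHBTc4 TS line against day 4 and against EGFP-TS3.5, and each day from day 2 on against the day before. Values after ± are the SE of the log2 fold change, or the SD where group means are given. The 24 gene lists were tested with limma's camera at a preset correlation of 0.01, with the Benjamini-Hochberg method over 264 tests, and again with an estimated correlation. Overlaps of calls that share the day 0 arrays were set against 100 simulations of unchanged groups and against independent lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

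The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those said below to have been added later. The text names Pou5f1, a fixed panel of genes, the 8 genes with the largest rise and the 8 with the largest fall among those that passed and whose arrays did not overlap between the groups (chance alone gives 10% of genes of 3 against 3 arrays without overlap), and the 4 members of each list with the largest absolute change; a gene outside this rule is said to be. The alternatives were other filters, quantile normalization, arrays centred on their medians, the mean of all probe sets of a gene, another variance model, array weights, a model of the 2 groups compared alone, the replicate number as a block, other fold requirements and leaving out each array. The procedure was tested on simulated data: for day 1 against day 0, 99 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were recovered, with 1 call among 14460 unchanged genes. For the ZHBTc4 TS line against EGFP-TS3.5 these were 99 and 100 of 100, with 0 calls among 14460. On lists simulated for day 4 against day 0, 4 of 4 lists shifted by 0.5 were called and 0 of the unshifted ones. The simulated genes varied independently of each other, so this could not show how correlated genes of a real list affect the calls.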

Results

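Gene expression was measured on 21 Affymetrix arrays of mouse stem cells, in 7 groups of 3 arrays. ZHBTc4 is an embryonic stem (ES) cell line of strain 129/Ola in which tetracycline (Tet) shuts off Oct3/4, the pluripotency factor encoded by Pou5f1. The groups were the ES cells on day 0, cells after 1, 2, 3 and 4 days of Tet in trophoblast stem (TS) cell medium with FGF4, heparin and Activin A, a TS line of ZHBTc4 cells under Tet, and EGFP-TS3.5, a TS line of strain ICR. The question addressed by the series was how gene expression moves when ES cells are turned into TS cells by repression of Oct3/4. The deposited log2 values were alike in range over the 21 arrays: the lower quartile was 6.26 to 6.33, the median 7.64 to 7.78 and the upper quartile 9.19 to 9.42. The labels call the arrays of a group biological replicates, and no label states whether they came from separate cultures. The p-values thus measure the spread between these arrays, pooled over the 7 groups, and the number of arrays limits the precision.

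Arrays of one group differed from each other by 0.128 to 0.250 (root mean square of the log2 differences over 14660 genes). The mean difference from day 0 was 0.344 on day 1, 0.460 on day 2, 0.480 on day 3 and 0.541 on day 4, against 0.661 for the ZHBTc4 TS line and 0.585 for EGFP-TS3.5. Day 4 lay at 0.403 from the ZHBTc4 TS line and at 0.439 from EGFP-TS3.5, and the TS lines lay at 0.551 from each other. Day 3 lay at 0.427 from the ZHBTc4 TS line and at 0.423 from EGFP-TS3.5, so the last day came no closer to EGFP-TS3.5. The first principal component held 41.3% of the variance and the next held 22.4%. Adjusted over the list alone, the counts of rising and falling members were those over all genes tested in 262 of the 264 tests of fixed gene lists; the 2 exceptions are given where they occur. Of 264 list tests, 116 were called, and 24 calls held with an estimated correlation: pluripotency genes in 8 comparisons, epithelial genes in 10, FGF and ERK response genes in 2, hypoxia and stress genes in 2, and fibroblast markers and interferon genes in 1 each. No called list had a median or mean that ran against the direction of its test, and no median of a called list turned sign under either other scaling of the arrays.

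**Figure D1:**
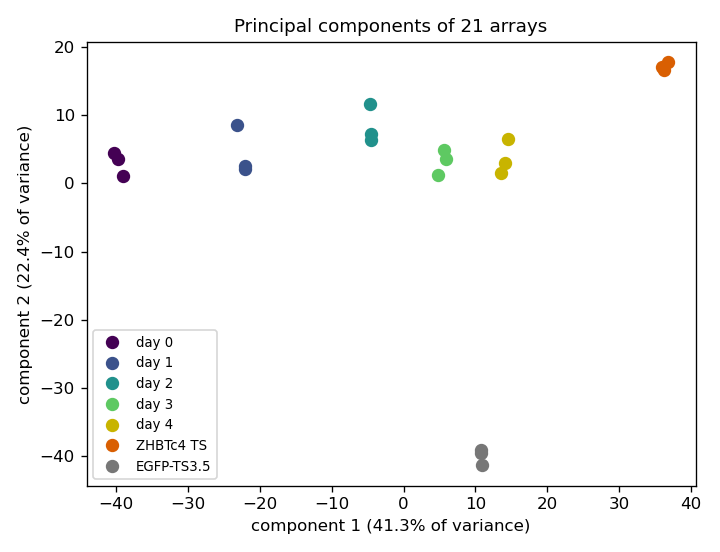
Scores of the 21 arrays on the first 2 principal components of the log2 values, with 41.3% and 22.4% of the variance; each point is an array, coloured by group. The 5 days of the course run in order from left to right, the ZHBTc4 TS line lies farthest right, and EGFP-TS3.5 lies apart from all other groups on the vertical axis.

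Pou5f1, the repressed gene, had a log2 level of 12.86 ± 0.10 (mean ± SD, n = 3) on day 0, 12.79 ± 0.078 on day 1, 12.23 ± 0.080 on day 2, 10.63 ± 0.145 on day 3 and 9.94 ± 0.14 on day 4. It stood at 8.24 ± 0.51 in the ZHBTc4 TS line and at 8.04 ± 0.40 in EGFP-TS3.5. The arrays labelled day 1 thus showed no lower Pou5f1 signal than day 0 beyond the spread, and which part of the transcript its probe set covers is not given in the sources used here. Nanog, a pluripotency factor, went from 13.18 ± 0.048 on day 0 to 13.08 ± 0.034, 12.04 ± 0.11, 8.52 ± 0.12 and 7.45 ± 0.13 on days 1 to 4. Cdx2, a transcription factor of the trophoblast lineage, was at 7.71 ± 0.13 on day 0, 9.77 ± 0.068 on day 1, 11.11 ± 0.070 on day 2 and 10.69 ± 0.17 on day 4. Elf5, a factor of TS cells, was at 6.90 ± 0.20 on day 0, 7.53 ± 0.19 on day 2, 8.34 ± 0.13 on day 3 and 9.44 ± 0.15 on day 4, and at 11.30 ± 0.027 and 12.15 ± 0.024 in the ZHBTc4 and EGFP-TS3.5 lines. The probe sets read here were 6850173 for Pou5f1, 6949706 for Nanog, 6943138 for Cdx2 and 6879610 for Elf5.

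**Figure D2:**
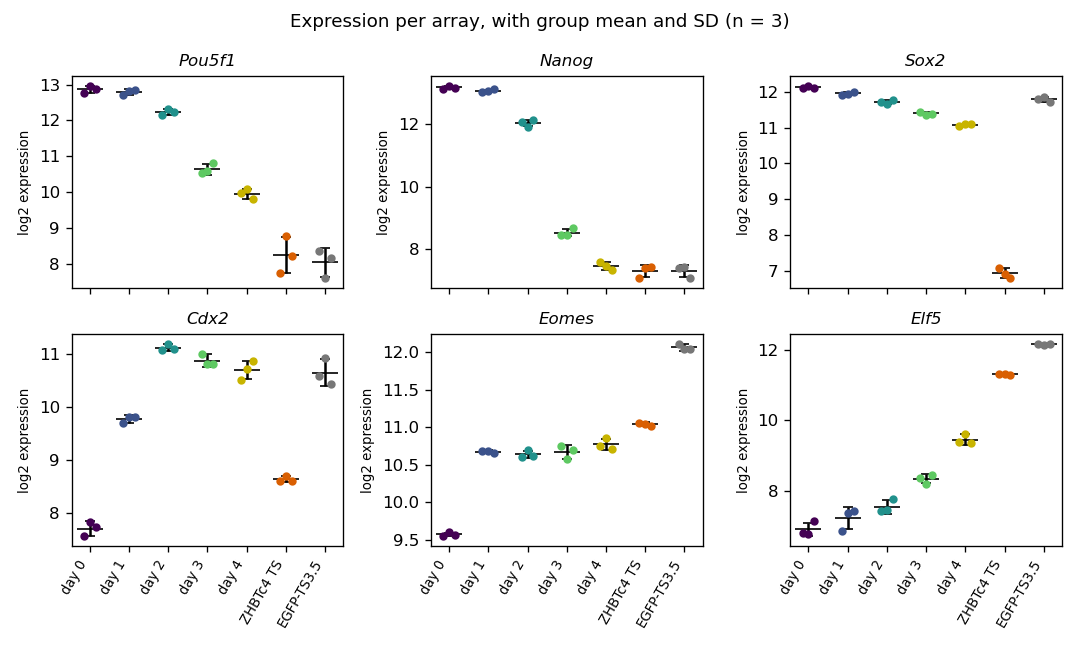
Log2 expression of Pou5f1, Nanog, Sox2, Cdx2, Eomes and Elf5 in the 7 groups; points are arrays, and bars are the group mean with its SD (n = 3). Pou5f1 fell from 12.86 on day 0 to 9.94 on day 4, and Sox2 was at 6.94 in the ZHBTc4 TS line against 11.79 in EGFP-TS3.5.

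On day 1, single trophoblast and epithelial junction genes were higher, while most members of both lists did not pass, and 10 of 27 pluripotency genes were lower. Pou5f1 itself differed by -0.077 ± 0.19 on the log2 scale (SE, adjusted p = 0.819) and Nanog by -0.11 ± 0.10 (adjusted p = 0.502), and neither passed. Cdx2 rose by 2.06 ± 0.11 (adjusted p = 7.16e-11), Hand1, which acts in trophoblast giant cells, by 1.99 ± 0.088, Eomes by 1.10 ± 0.050 and Tfap2c by 1.135 ± 0.058. The largest rises also held the serine protease gene Prss8 (2.11), the tight junction genes Cldn3 (1.93) and Cldn6 (1.77), Dmrt1 (1.91) and Penk (1.798). Among the largest falls were the amino acid transporter gene Slc7a3 at -3.52 ± 0.084, Cobl at -3.11, Tcl1 at -2.83, Jam2 at -2.79 and Trh at -2.55.

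In all, 222 genes passed, 76 of them higher and 146 lower. Of 27 pluripotency genes, 10 fell and 17 did not pass (camera adjusted p = 8.95e-16), with Tdgf1 at -2.43, Nr0b1 at -2.31 and Zfp42 at -1.38. Of 27 TS cell genes, 5 rose and 2 fell (adjusted p = 0.0030; adjusted p = 0.296 with an estimated correlation), with Bmp8b at 1.71, Esx1 at 1.65 and Lifr, a receptor of LIF, at -1.58. Among 21 epithelial junction genes, 5 rose and 16 did not pass (adjusted p = 4.34e-07; adjusted p = 0.0594 with an estimated correlation), with Cldn4 at 1.75 and the desmosome gene Dsc2 at 1.497. DNA methylation genes numbered 9, and 2 of them fell, namely Dnmt3l at -1.68 and Tet2 at -1.54 (adjusted p = 0.0046; adjusted p = 0.264 with an estimated correlation). Imprinted genes were called higher as a list of 21 (median 0.33, adjusted p = 9.24e-05; adjusted p = 0.0531 with an estimated correlation), though 1 member alone passed. Of 28 fibroblast markers none passed (0 in limma; 8 were higher and 8 lower at an unadjusted p under 0.05), and the median was -0.021. From day 0 to day 1 the medium changed as well, from ES medium with LIF to TS medium, so Tet and medium cannot be separated in any comparison with day 0.

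By day 2, Cdx2 stood 3.40 ± 0.11 above day 0 on the log2 scale (10.6-fold, adjusted p = 4.09e-14), and the trophoblast keratin gene Krt18 2.59 ± 0.087 above it. Pou5f1 was at -0.63 ± 0.19 (adjusted p = 0.0125), short of the fold requirement, while Nanog fell by 1.14 and Klf4, another pluripotency factor, by 1.27 on the log2 scale. Nxf7 (3.02), Dsc2 (2.91), Esx1 (2.90), Prss8 (2.73) and Cited1 (2.61) were among the largest rises. Tdgf1 (-4.46 ± 0.13), a co-receptor of Nodal signalling, Trh (-4.34), Nr0b1 (-3.97), Jam2 (-3.57) and Stmn2 (-3.29) were among the largest falls.

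The test was passed by 533 genes, 227 higher and 306 lower. Pluripotency genes fell in 16 of 27 cases (17 when adjusted over the list alone) and did not pass in 11 (camera adjusted p = 1.45e-15), including Gdf3 at -3.19. TS cell genes rose in 13 of 27 cases and fell in 2 (adjusted p = 1.30e-04; adjusted p = 0.187 with an estimated correlation), with Bmp8b at 2.56 and Gata3 at 1.34. The epithelial list had 9 rises among 21 genes, and 12 did not pass (adjusted p = 1.44e-09), with Cldn3 at 2.38 and Cldn4 at 2.27. Of 18 hypoxia and stress genes, 4 rose and 1 fell (adjusted p = 3.37e-05; adjusted p = 0.0594 with an estimated correlation): Chac1 (1.96) and Trib3 (1.36), targets of the ATF4 stress response, and Ddit4 (1.72) rose, and Adm fell by 1.21. Of 11 germline genes, 3 rose, among them Ddx4 (1.14) and Sycp1 (1.14), and 2 fell, Stk31 (-2.00) and Tdrd12 (-1.90), and the list was not called (adjusted p = 0.248). The calls of Ddx4 and Sycp1 ended with array weights (0.96 and 0.80) and without replicate 3 of day 2 (0.98 and 0.93), and without the array of each group farthest along the shared axis (0.90 and 0.71). Sycp1 was also at 0.92 without replicate 2 of day 0, at 0.98 without replicate 2 of day 2 and at 0.99 with the third quartile of each array as a covariate. Beside these changes, 4 of 28 fibroblast markers fell and 24 did not pass (median -0.32, adjusted p = 2.23e-06; adjusted p = 0.159 with an estimated correlation), with Acta2 at -1.28 and Tagln at -1.27.

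On day 3, Pou5f1 had fallen by 2.23 on the log2 scale (4.7-fold, adjusted p = 2.50e-08) and Nanog stood at -4.66 (adjusted p = 4.28e-16). Tdgf1 (-6.24 ± 0.13), Trh (-4.97), Nr0b1 (-4.53), Fbxo15 (-4.47) and Otx2 (-3.80), an epiblast factor, were among the largest falls. Krt18 (3.501 ± 0.087), Bmp8b (3.36), Dsc2 (3.25), the matrix protease gene Mmp9 (3.21) and Cdx2 (3.16) were among the largest rises, and Elf5 passed for the first time in the course, at 1.44 ± 0.13 (adjusted p = 4.07e-08).

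Here 588 genes passed, 224 higher and 364 lower. Pluripotency genes fell in 19 of 27 cases and did not pass in 8 (camera adjusted p = 5.03e-19). TS cell genes rose in 14 of 27 and fell in 1 (adjusted p = 1.12e-07; adjusted p = 0.0816 with an estimated correlation), and Gata3 was at 1.57. Epithelial genes rose in 11 of 21 cases and did not pass in 10 (adjusted p = 2.70e-15), Cldn3 at 2.53 and Cldn4 at 2.51. Genes of differentiated trophoblast rose in 4 of 15 cases and fell in 1 (adjusted p = 0.0032; adjusted p = 0.111 with an estimated correlation), with Nrk at 2.33 and Flt1, a receptor of VEGF, at 1.36. Fibroblast markers fell in 5 of 28 cases and did not pass in 23 (median -0.47, adjusted p = 8.74e-09; adjusted p = 0.0999 with an estimated correlation), with Postn at -1.27 and Col5a2 at -1.09.

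At the end of the course, most pluripotency genes measured were lower than on day 0, and most TS cell and epithelial genes were higher. Pou5f1 fell by 2.92 on the log2 scale (7.57-fold, adjusted p = 4.69e-10), Nanog by 5.73 (adjusted p = 2.39e-17), Tdgf1 by 5.99 and Otx2 by 4.00, and Fbxo15 stood at -5.3985. Sox2, a factor shared by ES and TS cells, was at -1.04 ± 0.061, and the shared factor Esrrb was at -0.85 ± 0.051 (adjusted p = 1.08e-10), short of the fold requirement. Elf5 rose by 2.55 ± 0.13 (adjusted p = 1.16e-11), Cdx2 by 2.98 ± 0.11, Hand1 by 2.26 ± 0.088, Gata3 by 1.95 ± 0.067 and Eomes by 1.20 ± 0.050. Nxf7 (4.13), Krt18 (3.76), Bmp8b (3.61), Dsc2 (3.36), Mmp9 (3.24) and Cited1 (3.15) were among the largest rises.

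Of 14660 genes tested, 804 passed, 300 higher and 504 lower. Among 27 pluripotency genes, 20 fell and 7 did not pass (camera adjusted p = 4.80e-17), and Nr0b1 was at -4.21. Among 27 TS cell genes, 17 rose and 1 fell (adjusted p = 5.29e-09; adjusted p = 0.0594 with an estimated correlation). In the epithelial list, 14 of 21 rose and 7 did not pass (adjusted p = 1.25e-15), with Cldn3 at 2.79 and Cldn4 at 2.71. Genes of differentiated trophoblast rose in 4 of 15 cases and fell in 1 (adjusted p = 5.76e-04; adjusted p = 0.0699 with an estimated correlation), with Nrk at 2.65, Dlx3 at 1.95 and Adm at -2.12. Of 21 imprinted genes, 3 rose, 2 fell and 16 did not pass (adjusted p = 0.0177, and adjusted p = 0.190 with an estimated correlation): Phlda2 (2.28), Peg3 (1.66) and the cell cycle inhibitor gene Cdkn1c (1.36) rose, and Grb10 (-1.70) was among those that fell. Of 9 DNA methylation genes, 3 fell and 6 did not pass (adjusted p = 0.0033; adjusted p = 0.242 with an estimated correlation), with Dnmt3l, a cofactor of de novo methylation, at -3.17 and Zfp57 at -1.37. Hypoxia and stress genes rose in 7 of 18 cases and fell in 1 (adjusted p = 6.15e-06; adjusted p = 0.0531 with an estimated correlation), with Ndrg1 at 2.23 and Chac1 at 1.55. Of 18 mesoderm genes none passed (0 in limma; 3 were higher and 5 lower at an unadjusted p under 0.05), with a list median of 0.013 (adjusted p = 0.974). Together with these groups, 8 of 28 fibroblast markers fell and 20 did not pass (median -0.78, adjusted p = 3.67e-11; adjusted p = 0.0594 with an estimated correlation), with Thbs2 at -1.54 and Col1a1, a collagen gene, at -1.40.

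Between day 1 and day 2, 103 genes passed, 48 higher and 55 lower: Nxf7 rose by 2.66 ± 0.13, Cpm by 1.89, Hoxc9 by 1.797, Krt18 by 1.76 and Cdx2 by 1.34 ± 0.11, while Tdgf1 fell by 2.04, Nr0b1 by 1.665 and Otx2 by 1.54. Chac1 (1.46) and Trib3 (1.20) rose in the same step. Between day 2 and day 3, 27 genes passed, 5 higher and 22 lower, with Nanog at -3.52 ± 0.10 (adjusted p = 3.30e-13), Pou5f1 at -1.60 ± 0.19 (adjusted p = 2.01e-05), Fbxo15 at -1.87, Mmp9 at 1.71 and Nrk at 1.35. Between day 3 and day 4, 6 genes passed: Elf5 rose by 1.10 ± 0.13 (adjusted p = 3.89e-05), and Cavin2 (-1.15), Sema3c (-1.11), Nanog (-1.07), Angptl7 (-1.04) and Lrp2 (-1.03) fell. Pou5f1 was at -0.555 ± 0.19 (adjusted p = 0.050) in the step to day 2 and at -0.69 ± 0.19 (adjusted p = 0.0334) in the last step, and passed in neither. Its SE pools the spread of all 7 groups, and its SD was 0.40 in EGFP-TS3.5. On days 1 to 4 its SD was 0.078, 0.080, 0.145 and 0.142, so this SE overstates the spread within the course. Both steps were short of the fold requirement in any case. The fibroblast list was called lower in the step to day 2 (median -0.31, adjusted p = 1.33e-12; adjusted p = 0.0531 with an estimated correlation), to day 3 (median -0.14, adjusted p = 0.0161; adjusted p = 0.468 with an estimated correlation) and to day 4 (median -0.31, adjusted p = 2.02e-14). The last step depended on single arrays: without replicate 2 of day 4, 11 genes passed, and with array weights 14. Without the array of each group farthest along the axis that arrays of a group share, 21 genes passed and Elf5 was at 0.95. Angptl7 and Lrp2 lay close to the fold requirement: they were at -0.98 and -0.98 after quantile normalization, Angptl7 at -0.997 with each array centred on its median and at -0.999 without replicate 3 of day 3, and Lrp2 at -0.99 both with centred arrays and without replicate 1 of day 4. With the third quartile of each array as a covariate, Sema3c was at -0.99 and Lrp2 at -0.96.

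EGFP-TS3.5, the reference TS line, was compared with the ES cells of day 0. Pou5f1 was lower by -4.83 ± 0.19 on the log2 scale (adjusted p = 3.39e-13), as were Tdgf1 (-6.08), Nanog (-5.89) and Fbxo15 (-5.56). Elf5 was higher by 5.25 ± 0.13 (38.1-fold, adjusted p = 4.39e-16), Cdx2 by 2.93 ± 0.11, Hand1 by 2.51 ± 0.088, Eomes by 2.48 ± 0.050 and Gata3 by 2.19. The cytokine receptor gene Il5ra (5.35 ± 0.078), Meig1 (4.32), Nat8l (4.31), the retinoic acid hydroxylase gene Cyp26a1 (4.11) and Prom1 (3.86) were among the largest differences upward. Sox2 differed by -0.33 ± 0.061 (adjusted p = 1.64e-04) and did not pass.

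The test was passed by 931 genes, 389 higher and 542 lower in EGFP-TS3.5. Of 27 pluripotency genes, 21 were lower and 6 did not pass (camera adjusted p = 1.02e-14). Of 27 TS cell genes, 13 were higher and 1 lower (adjusted p = 2.04e-10; adjusted p = 0.0529 with an estimated correlation), with Bmp8b at 3.80 and Mmp9 at 3.21. Epithelial genes were higher in 10 of 21 cases and did not pass in 11 (adjusted p = 3.25e-10), Cldn6 at 2.33 among them. Germline genes were lower in 8 of 11 cases and did not pass in 3 (adjusted p = 5.77e-04; adjusted p = 0.221 with an estimated correlation), with Hormad1 at -4.16 and Mael at -3.95. Genes downstream of LIF and STAT3 were lower in 5 of 11 cases and did not pass in 6 (adjusted p = 3.93e-04; adjusted p = 0.0531 with an estimated correlation), with Tfcp2l1 at -1.68 and Klf4 at -1.66. FGF and ERK response genes were higher in 2 of 16 cases and did not pass in 14 (adjusted p = 0.0083; adjusted p = 0.141 with an estimated correlation), Dusp4 at 1.53 and Spred2 at 1.08. Fibroblast markers were lower in 3 of 28 cases and did not pass in 25 (median -0.49, adjusted p = 2.86e-06; adjusted p = 0.162 with an estimated correlation). Strain, cell line and culture medium differ between these groups. Whether the TS lines were hybridised apart from the course is not given in the sources used here. In every comparison of either TS line with a day of the course, a batch of arrays therefore cannot be told apart from the group.

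In the ZHBTc4 TS line, Pou5f1 was lower than on day 0 by -4.62 ± 0.19 (log2, adjusted p = 3.90e-13), Nanog by -5.89 ± 0.10, Sox2 by -5.18 ± 0.061 (adjusted p = 3.89e-20) and Esrrb by -2.94 ± 0.051. Elf5 was higher by 4.40 ± 0.13 (adjusted p = 2.72e-15), Gata3 by 2.25, Tfap2c by 2.08 and Ascl2, which acts in trophoblast, by 2.23. Cdx2 was at 0.93 ± 0.11 (adjusted p = 5.27e-07), short of the fold requirement, and at 1.003 without the array of each group farthest along the shared axis. Nxf7 (5.47), Tmprss2 (4.77), the placental gene Plac1 (4.67), Dsc2 (4.27), Krt18 (4.27) and Prss8 (4.12) were among the largest differences upward. Hormad1 (-5.85), a meiosis gene, Fbxo15 (-5.74) and Nr0b1 (-4.98) were among the largest downward, and the Y-linked gene Eif2s3y was lower by -3.11 ± 0.14.

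Of the genes tested, 1303 passed, 734 higher and 569 lower. Pluripotency genes were lower in 20 of 27 cases (21 when adjusted over the list alone) and did not pass in 7 (camera adjusted p = 8.95e-16). TS cell genes were higher in 15 of 27 and lower in 2 (adjusted p = 1.79e-09; adjusted p = 0.0573 with an estimated correlation), with Dppa1 at 3.92. Among 21 epithelial genes, 18 were higher and 3 did not pass (adjusted p = 8.56e-16), with Dsp at 3.46 and Cldn7 at 3.45. FGF and ERK response genes were lower in 6 of 16 cases and did not pass in 10 (adjusted p = 4.39e-04; adjusted p = 0.0594 with an estimated correlation), among them the feedback inhibitor gene Spry4 at -2.31 and the ETS factor genes Etv5 at -2.30 and Etv4 at -2.08. Hypoxia and stress genes were higher in 7 of 18 cases and lower in 1 (adjusted p = 1.71e-06), with Ndrg1 at 3.36 and Atf3 at 2.51. Germline genes were lower in 7 of 11 cases and did not pass in 4 (adjusted p = 0.0023; adjusted p = 0.266 with an estimated correlation). Fibroblast markers were lower in 10 of 28 cases and did not pass in 18 (median -0.74, adjusted p = 2.75e-08; adjusted p = 0.111 with an estimated correlation), with S100a4 at -1.99 and Col1a1 at -1.28.

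Compared with day 4 of the course, the ZHBTc4 TS line had lower Sox2 (-4.14 ± 0.061 on the log2 scale, 17.7-fold, adjusted p = 1.93e-18), Esrrb (-2.08 ± 0.051) and Cdx2 (-2.05 ± 0.11, adjusted p = 4.99e-11). Pou5f1 was lower by -1.70 ± 0.19 (adjusted p = 1.27e-06) and Hand1 by -1.48 ± 0.088, while Elf5 was higher by 1.85 ± 0.13 and Ascl2 by 1.34 ± 0.091. BC053393 (4.21), B4galnt2 (3.52), Slc7a3 (3.40), Popdc3 (3.14), the epithelial trafficking gene Rab25 (3.09) and Satb1 (2.71), a chromatin organiser, were among the largest differences upward. The histone gene H2ac1 (-3.475), Hormad1 (-3.325), Eif2s3y (-3.04 ± 0.14), Mmp9 (-2.95), Mael (-2.73), which acts in germline transposon silencing, and Hprt (-2.39 ± 0.18), an X-linked gene of purine salvage, were among the largest downward.

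In this comparison 372 genes passed, 294 higher and 78 lower in the line. The median over all genes was 0.0025 with the deposited values, -0.062 with arrays centred on their medians and -0.077 after quantile normalization. The balance of higher and lower genes may therefore depend on the scaling. Of 16 FGF and ERK response genes, 3 were lower and 13 did not pass (camera adjusted p = 2.28e-08, median -0.42), and these were Spry4 at -2.04 ± 0.052, Etv5 at -1.74 and Etv4 at -1.51. Epithelial genes were higher in 6 of 21 cases and did not pass in 15 (adjusted p = 2.42e-10), with the tight junction genes Ocln at 1.37 and Tjp3 at 1.22. TS cell genes went both ways, with 5 of 27 higher, among them Dppa1 (2.66) and Plac1 (2.15), and 4 lower (adjusted p = 0.0044; adjusted p = 0.318 with an estimated correlation; median 0.45). Germline genes were lower in 6 of 11 cases and did not pass in 5 (adjusted p = 3.72e-05; adjusted p = 0.141 with an estimated correlation), including Ddx4 at -1.66. Of 28 fibroblast markers none passed (0 in limma; 10 were higher and 8 lower at an unadjusted p under 0.05), with a median of 0.061.

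Between the TS lines, Pou5f1 differed by 0.21 ± 0.19 (log2, ZHBTc4 TS minus EGFP-TS3.5, adjusted p = 0.384) and did not pass; it was at -0.052 without replicate 2 of the ZHBTc4 line and at -0.015 without replicate 2 of EGFP-TS3.5. The ZHBTc4 line had lower Sox2 (-4.86 ± 0.061, adjusted p = 1.22e-19), Esrrb (-3.02 ± 0.051), Cdx2 (-2.00 ± 0.11), Hand1 (-1.73 ± 0.088) and Nr0b1 (-5.49 ± 0.12), and lower Kdr, a receptor of VEGF, at -2.93. For Nr0b1 this was more than its difference between the ZHBTc4 line and day 0, so Nr0b1 was not lower in EGFP-TS3.5 than on day 0. Gata3 was at 0.060 ± 0.067 (adjusted p = 0.465) and did not pass, and its sign turned after quantile normalization (-0.073), with each array centred on its median (-0.0044) and with the third quartile of each array as a covariate (-0.057). Elf5 was at -0.85 ± 0.13 (adjusted p = 2.12e-05) and did not pass, except with the third quartile of each array as a covariate (-1.14). Ascl2 was higher in the ZHBTc4 line by 2.89 ± 0.091, Slc7a3 by 4.48, Plac1 by 4.36, Tmprss2 by 4.62, Nxf7 by 4.16, Prtg by 4.11 and Dppa1 by 3.85. Il5ra (-5.04), Cyp26a1 (-3.60), Nat8l (-3.59) and Gdf6 (-3.46) were among the largest differences downward.

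The test was passed by 819 genes, 541 of them higher in the ZHBTc4 line and 278 lower; after quantile normalization these were 440 higher and 366 lower. FGF and ERK response genes were lower in 10 of 16 cases and did not pass in 6 (camera adjusted p = 5.33e-11, median -1.10), with Spry4 at -2.63 ± 0.052, Etv4 at -1.90 and Etv5 at -1.86. Epithelial genes were higher in 13 of 21 cases and did not pass in 8 (adjusted p = 9.95e-12), with Ocln at 2.53, Tjp3 at 2.26 and the splicing factor gene Esrp1 at 2.19. Of 27 TS cell genes, 9 were higher and 7 lower (adjusted p = 0.595), Mmp9 at -2.92 and Bmp4 at -2.56 among the latter. Hypoxia and stress genes were higher in 4 of 18 cases and did not pass in 14 (adjusted p = 2.78e-06; adjusted p = 0.0511 with an estimated correlation), with Ndrg1 at 2.43, Atf3 at 2.17 and Vegfa at 1.16. Imprinted genes were higher in 6 of 21 cases, among them Phlda2 (1.95), and lower in 2, among them Grb10 (-2.69), while 13 did not pass and the list was not called (adjusted p = 0.302). Epiblast genes were lower in 3 of 10 cases and did not pass in 7 (adjusted p = 0.0072; adjusted p = 0.0552 with an estimated correlation), namely Pou3f1 (-1.63), Zic2 (-1.54) and Sfrp2 (-1.16). Of 28 fibroblast markers none passed (0 in limma; 6 were higher and 17 lower in the ZHBTc4 line at an unadjusted p under 0.05), with a median of -0.27 (adjusted p = 0.0032; adjusted p = 0.368 with an estimated correlation). The lines are of different strains, so line, strain and origin cannot be separated here.

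**Figure D3:**
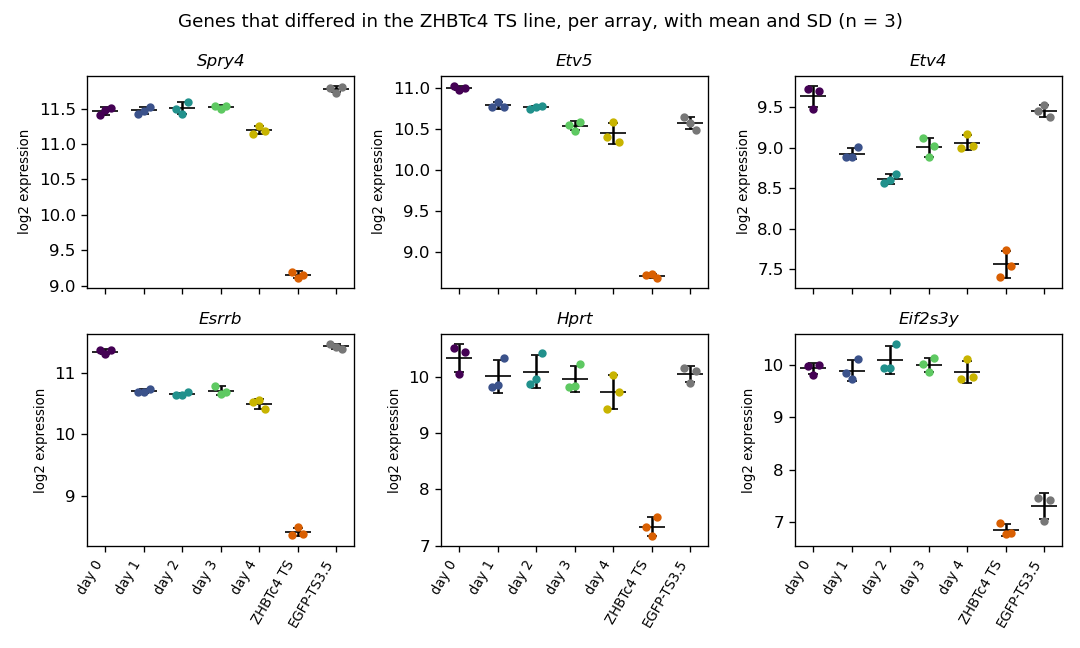
Log2 expression of Spry4, Etv5, Etv4, Esrrb, Hprt and Eif2s3y in the 7 groups; points are arrays, and bars are the group mean with its SD (n = 3). Hprt was at 7.17 to 7.52 in the ZHBTc4 TS arrays against 9.43 to 10.52 in the 15 arrays of the course, and Eif2s3y was low in both TS lines.

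Genes that changed by day 4 were set against those that set EGFP-TS3.5 apart from day 0. Both comparisons passed in the same direction for 455 genes, 133 higher and 322 lower, and in opposite directions for 6. Independent lists of these sizes would share 8.0 higher and 18.6 lower genes, and 100 simulations of unchanged groups against the shared day 0 arrays gave 0 shared genes (limma; the highest of the draws was 0). Unchanged groups give almost no passing genes, so this 0 was nearly fixed in advance. It does not measure what the shared arrays add between groups that did change. The log2 fold changes of all tested genes had a correlation across genes of 0.714 (0.498 in the simulation, where genes are not independent replicates) and a covariance of 0.210 against a simulated 0.0055. For the ZHBTc4 TS line and EGFP-TS3.5, each against day 0, 486 genes passed in the same direction, 163 higher and 323 lower, and 13 in opposite directions. Independent lists would share 19.5 and 21.0, and the simulation gave 0, with the same limit. The correlation was 0.623 (0.501 simulated) and the covariance 0.229 (0.0056 simulated). The 3 arrays of day 0 cannot be divided into parts of at least 2, so part of the excess may come from the shared day 0 arrays.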

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

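The search for genes that passed in opposite directions in the TS lines and the test of probe sets without a listed gene were chosen after the data were seen; the comparison of the lines and the list tests were fixed earlier. Against day 0, 13 genes passed in opposite directions in the 2 TS lines (limma); the lines thus differed in each by construction, so no p of that difference is given. Elf3, an epithelial factor singled out after its values were seen, was at 2.69 in the ZHBTc4 line and at -1.06 in EGFP-TS3.5 on the log2 scale. The imprinted gene Grb10 was at -1.60 and 1.09, and Prtg was at 1.23 and -2.88.

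The median of the FGF and ERK response genes differed between the TS lines by -1.10 on the log2 scale (16 genes, 10 lower and 6 not passing; camera adjusted p = 5.33e-11, and adjusted p = 0.0040 with an estimated correlation). The lines carried the same label of FGF4, heparin and Activin A in the medium.

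Among probe sets without a listed gene, which no comparison used, 227 of 7012 above the filter passed between day 4 and day 0, 95 higher and 132 lower, or 3.24% against 5.48% of the named genes. The share was lower than that of named genes in 10 of the 11 comparisons and higher between the TS lines (6.99% against 5.59%). Those that passed were mostly higher in the ZHBTc4 line: 460 against 30 lower relative to EGFP-TS3.5, 417 against 106 relative to day 0, and 136 against 16 relative to day 4. In EGFP-TS3.5 against day 0, 51 were higher and 119 lower. The cause was not tested. No difference between these shares was tested, and no other scaling of the arrays was tried on these probe sets.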

How the results depend on the processing

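Of the alternatives below, the third quartile of each array as a covariate and leaving out the array of each group farthest along a shared axis were chosen after seeing the data; the others were planned, and all planned ones were run. The replicate numbers of the titles were not taken as pairs, and no label says that they are: the mean correlation of the deviations of same-numbered arrays was -0.022, 0.060 and 0.075 for numbers 1 to 3 (-0.019 between different numbers), and 12 of 21 arrays correlated best with arrays of their own number, so a weak shared part of numbers 2 and 3 stays open. With the replicate number as a block, 222, 534, 587 and 804 genes passed for days 1 to 4 against day 0, 1303 and 931 for the ZHBTc4 and EGFP-TS3.5 lines against day 0, 372 for the ZHBTc4 line against day 4, 819 between the lines, 103, 27 and 6 in the steps, and 116 list tests were called, 115 of the 116 calls among them. No count of genes moved by over 1.5 times with only the 2 groups compared in the fit or with other filters, scalings, probe set rules or variance models; array weights gave 14 genes instead of 6 for day 4 against day 3, leaving out the farthest arrays 21 and leaving out replicate 2 of day 4 alone 11; the cause was not tested. The estimate of the array weights stopped before its convergence tolerance was reached, so values with array weights are approximate. Between the TS lines, quantile normalization gave 440 higher and 366 lower genes, and the third quartile as a covariate 441 and 407, against 541 and 278.

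By construction, requiring an adjusted p alone raised the counts to 4434, 6529, 6289 and 7174 for days 1 to 4, 8488 for the ZHBTc4 line and 7823 for EGFP-TS3.5 against day 0, 5902 for the ZHBTc4 line against day 4, 7844 between the lines and 3097, 2651 and 1283 in the steps. An absolute log2 fold change of at least 2 left 27, 77, 118 and 149 genes for days 1 to 4, 284 and 191 for the lines, 45, 156, and 3, 2 and 0 in the steps (limma; 0 also at an unadjusted p under 0.05, where the largest change from day 3 to day 4 was -1.15). At an adjusted p alone, day 4 and EGFP-TS3.5 shared 4694 genes in direction, with 566 in opposite directions. Independent lists would share 806.9 higher and 1118.4 lower genes. The TS lines shared 4864, with 907 in opposite directions, where independent lists would share 1048.8 and 1205.7. With an estimated correlation, 24 list tests were called in place of 116.

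Leaving out each array in turn gave 217 to 248 genes on day 1, 529 to 556 on day 2, 586 to 602 on day 3, 780 to 842 on day 4, 1296 to 1320 for the ZHBTc4 line and 919 to 951 for EGFP-TS3.5 against day 0, 356 to 416 for the ZHBTc4 line against day 4, 811 to 835 between the lines, and 99 to 107, 24 to 30 and 5 to 11 in the steps; the highest of the last step came without replicate 2 of day 4. Named genes kept their direction and side of the threshold in 3025 of 3043 values under other settings (12 fell below it, 3 passed and 3 turned sign) and in 1653 of 1662 without an array (7 fell below it and 2 turned sign). Pou5f1, which differed by 0.21 between the TS lines without passing, lay between -0.052 without replicate 2 of the ZHBTc4 line and 0.45 without its replicate 1, and was at -0.015 without replicate 2 of EGFP-TS3.5. Gata3, which differed between the lines by 0.060 without passing, was at -0.073 after quantile normalization, -0.0044 with arrays centred on their medians and -0.057 with the third quartile of each array as a covariate. Dim signal limits what can be seen: genes not above the filter value of 6.29 on at least 3 arrays were not tested. A tested gene could lie below that value in a group, as Nxf7 did on day 0 (6.17), and its change may then be understated.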

Other observations

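Of the germline histone genes looked at, H2ac1 and H2bc1 had their highest mean on day 2, and H1f6 did not pass there (-0.31, adjusted p = 0.0967). The log2 level of H2ac1, which encodes a testis histone, was 11.38 ± 0.19 (SD, n = 3) on day 0, 12.98 ± 0.071 on day 2, 12.07 ± 0.071 on day 4, 8.59 ± 0.36 in the ZHBTc4 TS line and 8.50 ± 0.090 in EGFP-TS3.5. Its partner H2bc1 was at 9.09 ± 0.16 on day 0, 10.9998 ± 0.11 on day 2, 9.80 ± 0.14 on day 4, 7.86 ± 0.55 in the ZHBTc4 line and 7.03 ± 0.073 in EGFP-TS3.5. Both rose from day 0 to day 2 (1.60 and 1.91 on the log2 scale; limma adjusted p = 1.00e-08 and 1.35e-07) and were lower in both lines than on day 0 (H2ac1 -2.78 and -2.88, H2bc1 -1.23 and -2.06). Without replicate 2 of the ZHBTc4 line, H2bc1 was at -0.96 there. These genes were singled out for this paragraph after their values were seen.

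Of the primitive endoderm list, the factors Gata4 (0.35), Gata6 (-0.10) and Sox17 (0.16) did not pass on day 4, and of its 22 genes tested 1 rose, 3 fell and 18 did not pass (camera adjusted p = 0.524): Pth1r was at 2.52 ± 0.061 on the log2 scale, Lrp2 at -2.16, Lama1 at -2.07 and Apoe at -1.26. Of 12 glycolysis genes, 1 rose on day 4, and 11 did not pass (camera adjusted p = 0.397), with Hk1 at 0.86 and Pfkp at -0.85. The lactate exporter gene Slc16a3 was at 1.08 ± 0.079 on day 4 and was at 1.89 in the ZHBTc4 line and 2.22 in EGFP-TS3.5 against day 0. The glucose transporter gene Slc2a3 was at 0.91 ± 0.056 on day 4, which did not pass, and was lower in EGFP-TS3.5 than on day 0 by -1.79 ± 0.056. Of 11 genes downstream of LIF and STAT3, 2 fell by day 4, Osmr (-1.74) and Klf4 (-1.72), and 9 did not pass (camera adjusted p = 0.0067, and adjusted p = 0.111 with an estimated correlation). Of 16 FGF and ERK response genes, 1 fell, Spry2 (-1.503), and 15 did not pass (camera adjusted p = 0.316).

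The tests of this part were chosen after the result was seen, except those of other splits, of saturation and of the share of feeder RNA. For each of the 11 comparisons, 1 of the 10 splits of its 6 arrays, the real one, gave as many passing genes: 222, 533, 588 and 804 for days 1 to 4, 1303 and 931 for the lines against day 0, 372, 819, 103, 27 and 6, where the highest other split gave 0 (limma; at an unadjusted p under 0.05 and the same fold, at most 13). These 10 splits are too few for a share under 0.05.

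Arrays of one group differed along one shared axis that held 41.0% of the variance within groups. It followed the third quartile of the arrays, both as deviations from the group mean (21 arrays, Pearson r = 0.991, permutation p = 2.00e-05; rho = 0.978, permutation p = 1.00e-05, the smallest that 100000 resamples can give; r = 0.986 without the 2 farthest; adjusted p = 4.00e-05 over 2 relations). The quartile and the axis come from the same values, so this test largely measured the axis again and backs no cause: a stretch of the upper range cannot be told apart from other causes. The mean of the fibroblast list met the threshold written beforehand for feeder RNA (r = 0.787, permutation p = 0.0034; rho = 0.782, permutation p = 0.0033; r = 0.821 without the 2 farthest; adjusted p = 0.0034), but random lists of like brightness had a median r of 0.889, so that test was not specific, and its slope at the 44.5th percentile of 10000 such lists argues against feeder RNA beyond what they show. Arrays of replicate number 1 did not deviate together (mean correlation -0.022, the lowest), and numbers 2 and 3 were at 0.060 and 0.075. This met the bound written against a batch marked by all numbers, but a batch that left number 1 in the middle would meet it too. On the axis, replicate 2 was negative on days 0 to 3 (-10.7, -9.9, -6.2 and -7.8) and at 12.6 on day 4. Replicate 3 was positive on days 0 to 3 (2.6, 16.3, 15.4 and 6.6) and at -4.6 on day 4. A batch by replicate number thus stays open. A feeder share of unknown size stays open, with Acta2 at 12.71, Fstl1 at 11.95 and Col1a1 at 11.64 on day 0. In the ZHBTc4 line, 28 of the 28 list genes lay above the filter value, and 0 were in another list. The feeder tests covered deviations within groups and do not bound a change of feeder RNA between day 0 and the other groups. Labels conflict on whether the ES cells grew on feeders, no sort is named, and no biological explanation was tested.

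In the ZHBTc4 TS line, Y-linked Eif2s3y was at 6.76 to 6.98 and X-linked Hprt at 7.17 to 7.52, against 9.73 to 10.41 and 9.43 to 10.52 in the 15 arrays of the course and 7.02 to 7.46 and 9.90 to 10.16 in EGFP-TS3.5. An exchange of the arrays of the TS lines needs EGFP-TS3.5 at the level of the course. Eif2s3y differed there from day 4 by -2.58, but Hprt there lay within the range of the course. The Eif2s3y values thus argue against an exchange alone. An exchange together with a loss of the Eif2s3y signal in the line cannot be excluded. Feeder RNA as the source of Eif2s3y in the course needs a fall with the fibroblast list, whose median moved by -0.78 to day 4, but Eif2s3y moved by -0.063. Y-linked Kdm5d, also tested, went the other way and moved by -0.57 (limma adjusted p = 7.44e-06). It was dim, at 6.56 on day 0 and 5.98 on day 4, near the filter value of 6.29. The argument thus covers Eif2s3y alone, and a feeder part in Kdm5d stays open. Arrays of another line labelled as the ZHBTc4 TS line cannot be told apart from a change in the line itself: its arrays lay farther from EGFP-TS3.5 than from day 4 by 0.148, which an unrelated line could show as well. A loss of the Y chromosome in culture stays open and untested, as does the cause of the low Hprt.

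Pou5f1 was hardly lower on day 1, for which saturation of bright probe sets may be one reason. Of 46 genes as bright as Pou5f1 on day 0 or brighter, 0 fell by at least 1 on the log2 scale (limma), against 91 of 6066 genes from a level of 9 up to that of Pou5f1 (one-sided exact Fisher p = 0.5003). That share decides nothing, but Zfp57, at 12.85 on day 0 against 12.86 for Pou5f1, was lower on day 1 by -0.98 (adjusted p = 7.97e-10, short of the fold requirement except after quantile normalization, at -1.005), and Tdgf1, at 12.44, fell by 2.43. These genes, looked at after their values were seen, argue against a ceiling that all probe sets share at that brightness. For the probes of Pou5f1 itself, saturation and a late loss of the RNA cannot be told apart. Whether RNA of the disrupted Oct3/4 alleles adds to the signal was not tested.

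Over genes with a mean above 9, X-linked genes were higher in the ZHBTc4 TS line: their median difference to day 4 was 0.28 (172 genes, 76.2% higher), against 0.010 to 0.16 over the autosomes, and it was 0.27 against day 0 and 0.31 against EGFP-TS3.5. The test of X dosage measured again the pattern that prompted it, so it backs no cause, and with an estimated correlation the list was not called (camera adjusted p = 0.9997). That value was the same for every chromosome in every comparison made, so this setting decides nothing. X dosage cannot be told apart from other causes here, and Xist was not tested.

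Genes of chromosomes 6 and 11 were higher in EGFP-TS3.5, for which extra copies may be one reason; this test too measured the pattern again and backs no cause. Against day 0 the median was 0.14 over 545 genes of chromosome 11 (camera adjusted p = 4.40e-04) and 0.093 over 279 genes of chromosome 6 (adjusted p = 0.0407), against -0.15 to -0.018 over the other autosomes. Against day 4 it was 0.12 for chromosome 11 (camera adjusted p = 0.0012) and 0.11 for chromosome 6 (adjusted p = 0.0098). The other autosomes were at -0.14 to 0.048 there. Both comparisons use the same EGFP-TS3.5 arrays, so the second is no separate test. The requirement that both chromosomes pass against the ZHBTc4 line too was not met (chromosome 11 -0.058, adjusted p = 0.0281; chromosome 6 -0.044, adjusted p = 0.194; other autosomes 0.11 to 0.20). Both had the lowest medians there and a missed p excludes nothing, so the label of this test, first written as excluded, was left open after the value was seen. No chromosome call held with an estimated correlation (adjusted p = 0.9997 for every chromosome), a setting that decides nothing here, and strain differs too.

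Germline genes had a median of 0.63 over 11 genes, 9 of them above 0, for day 2 minus the mean of days 0 and 4. This contrast was chosen after the pattern was seen and restates it, so it does not back a short rise of these genes; the planned list test of day 2 against day 0 was not called (camera adjusted p = 0.248).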
